A study of Mus musculus with 21 samples.

How the data were processed

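RNA was sequenced from the brains of mice at postnatal day 57. The model deletes Pdcd10 in brain endothelium. The knockouts carried floxed Pdcd10 alleles, an inducible Cre recombinase under the Slco1c1 promoter, and the astrocyte reporter Aldh1l1-EGFP/Rpl10a, which tags ribosomes. The controls, called Flox in the labels, carried the floxed alleles and the reporter. In the sample records used here, 50 micrograms of 4-hydroxytamoxifen on postnatal day 1 are given for the knockouts, and no dose is given for the controls. Genotype and injection can therefore not be told apart in the knockout comparisons. The series' design text also names Cre-carrying animals without an injection as controls and does not say which samples they were. Animals were kept at 21% oxygen or at 12% oxygen for 7 days. The design text describes pull-down of tagged astrocyte ribosomes, while the extraction text of the samples describes brain tissue homogenised for total RNA, so the text below speaks of astrocyte-enriched RNA only as far as the marker genes show it. All samples carry the tag male.

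The labels list 21 samples and counts of 19 were used: 4 knockout and 4 control libraries in normoxia, 7 knockout and 4 control libraries in hypoxia. Control hypoxia replicates 1 and 2 were not analysed here, so a design written for 21 libraries was run on 19. The authors deposited whole-number counts per gene; per the submitters' processing notes, HISAT2 and edgeR were used with the mouse build GRCm39, with no versions given. The counter, and whether it used strand, is not given in the sources used here. The authors also deposited RPKM values, which equal the counts divided by the column total and by 1 length per gene, to a relative difference of at most 7.4e-15; no test used them. Totals ranged from 45399320 to 65261791 counts per library. They include a gene ID not named here, which held 0.156 to 0.562% of counts and was not removed before the tests. Among counts of 2 to 21, 65.9% were even, as would arise if both mates of a pair were counted, so counting precision is lower than the totals imply. Of 55416 gene IDs, 52083 matched a symbol in the name table. Neighbouring genes were read from the RefSeq annotation of GRCm38.p6, a different build, and no coordinates are given.

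Genes were kept by filterByExpr, which left 19854. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust dispersion) in 1 fit of all 19 libraries with 4 group terms. The 5 contrasts were knockout against control at each oxygen level, hypoxia against normoxia in each genotype, and their interaction. A call is a Benjamini-Hochberg adjusted p under 0.05. Levels are counts scaled by TMM-normalised library size (CPM), given as mean ± SD with the number of libraries; log2 fold changes are given ± SE. The labels do not say that each library is a separate animal, so p-values measure the spread between these libraries. Genes with near-identical copies, among them the globins, histocompatibility genes, ribosomal protein genes, Ccl21a, C4b and Serpina3n, may have shared or lost reads, and their levels are uncertain.

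Before the data were examined, 37 gene lists were fixed, 21 of pathways and states and 16 of cell type markers; 36 had at least 3 genes tested. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all 180 list tests. The rule for named genes was also fixed then. It takes, per contrast, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and an established symbol, up to 4 members per list by adjusted p (up to 2 by p where none passed), and Pdcd10, Rpl10a, Slco1c1, Aldh1l1, Cx3cl1, Vegfa, Ptgs2, Gfap, Xist and Ddx3y. The text names the first 2 members of lists that changed. Agreement between contrasts that share no library was measured by the correlation of log2 fold changes across genes, which are not independent replicates.

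Whether replicate numbers pair samples was checked from the correlation of deviations from group means. For knockout against control in hypoxia the 4 shared numbers correlated at 0.12 to 0.27, all above the limit of 0.1 set beforehand, so the numbers were taken to pair those libraries, from the data and not from the labels. In the other comparisons the lowest correlation was between -0.25 and 0.02. The main fit did not use the pairs in hypoxia. The Fos and Fkbp5 levels given at the end cut across these numbers, so the pairing is uncertain. The closest replicates, knockout hypoxia 4 and 5, had a median chi-square of 1.9 per gene against 0.45 from sampling of independent counts. That expectation is too low if both mates of a pair were counted. Each library was counted separately, and whether this pair came from the same animal was not settled.

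The alternatives were RLE scaling, 2 other filters on low counts, DESeq2 1.42.0, limma-voom with sample weights, fits of the 2 groups alone, a replicate block, a minimum fold change, camera with an estimated correlation, fry, and leaving out each library. The replicate block was fitted by number over all 19 libraries. It therefore joined normoxic and hypoxic libraries of the same number and did not test the 4 hypoxic pairs alone. Chosen after seeing the data were a fit without knockout hypoxia libraries 1, 2 and 3 and fits with the neuron marker mean or the presence of Y-linked RNA as a covariate. The code was tested on simulated counts with 200 changed genes per contrast. Genes of the lowest levels were not among the changed ones. Counts were drawn independently for each gene, without the structure between libraries seen in these data. The shares recovered or false may therefore differ in the real counts. Of genes changed 2-fold, 77.6% were recovered for knockout against control in normoxia, 79.1% for the same in hypoxia, 80.6% for hypoxia in controls, 92.5% for hypoxia in knockouts and 73.1% for the interaction, over 19665, 19662, 19666, 19654 and 19663 simulated genes tested.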

Results

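The libraries measure polyadenylated RNA of the mouse brain in a model of cerebral cavernous malformation, in which Pdcd10 is deleted in brain endothelium by an inducible recombinase under the Slco1c1 promoter. The series asks how astrocytes differ in this disease in normoxia and after 7 days at 12% oxygen. There were 4 knockout and 4 control libraries in normoxia, and 7 knockout and 4 control libraries in hypoxia, with 45399320 to 65261791 counts each. Astrocyte genes led every library: the most counted gene was Glul, Gfap or Aldoc, and the median astrocyte marker lay between 402 and 1040 CPM.

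The targeted gene, Pdcd10 (ENSMUSG00000027835), was lower in every knockout library than in every control library. It measured 21.9 ± 1.8 CPM (SD, n = 4) in normoxic controls and 8.8 ± 1.17 CPM (n = 4) in normoxic knockouts, and 27 ± 2.85 CPM (n = 4) and 9.54 ± 1.79 CPM (n = 7) in hypoxia. The log2 fold change was -1.32 ± 0.14 in normoxia (edgeR adjusted p = 4.08e-05) and -1.5 ± 0.12 in hypoxia (adjusted p = 1.02e-06). Ddx3y, a Y-linked gene, was at most 3.24 CPM in 5 libraries (control normoxia 3 and 4, knockout hypoxia 6 and 7, control hypoxia 6) and at least 49.4 CPM in the others, although all samples carry the tag male. Xist was at most 0.946 CPM in every library. Among hypoxic controls it was 0.492 CPM in replicate 6, which lacked Y-linked RNA, and 0 to 0.0691 CPM in the others. These low levels do not settle the sex of the libraries. Rpl10a, the tagged ribosomal protein, and Aldh1l1, the astrocyte gene that drives the tag, did not pass in either knockout comparison (Rpl10a -0.45 ± 0.24 and -0.6 ± 0.21, Aldh1l1 -0.2 ± 0.13 and -0.29 ± 0.11 in normoxia and hypoxia). In hypoxia Rpl10a had an adjusted p of 0.0506 and was called without control hypoxia replicate 6 (-0.73), without knockout hypoxia replicate 1 or 4 (-0.67) or 5 (-0.65), and without knockout normoxia replicate 1 (-0.6). Aldh1l1 was called without knockout hypoxia replicate 4 or 7 (-0.34) or 5 (-0.33).

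**Figure D1:**
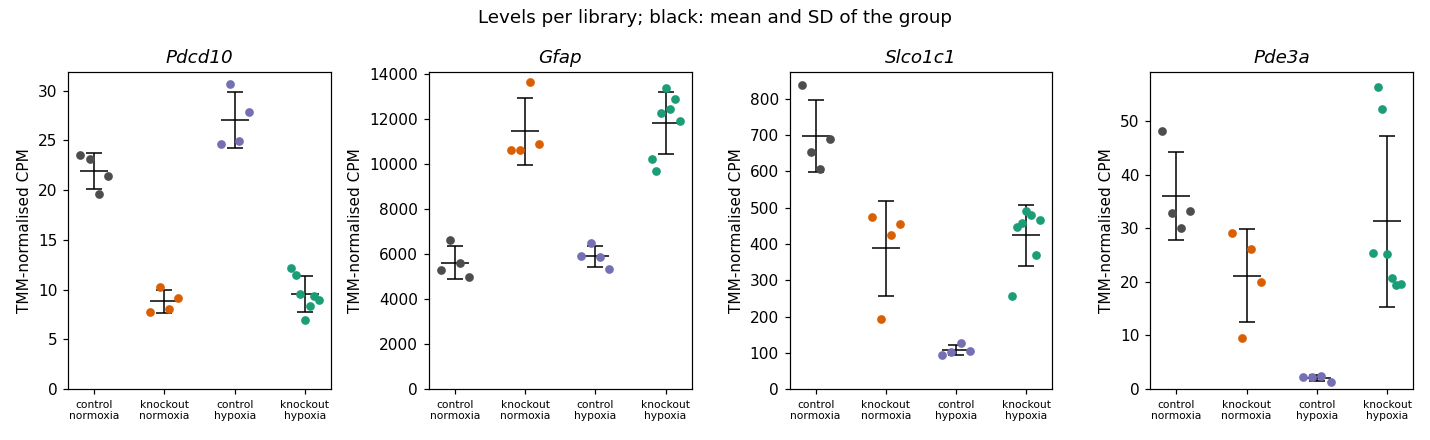
TMM-normalised CPM of Pdcd10, Gfap, Slco1c1 and Pde3a in each of the 19 libraries (points), with the mean and SD of each group in black. Pdcd10 is lower and Gfap higher in knockouts at both oxygen levels, while Slco1c1 and Pde3a are lowest in the control hypoxia libraries.

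The first comparison asked how knockouts differed from controls in normoxia. Gfap, an intermediate filament of reactive astrocytes, rose by a log2 of 1.03 ± 0.12, from 5610 ± 721.3 to 11450 ± 1472 CPM (SD, n = 4 each), and Vim, another such filament, by 1.41 ± 0.14. Among called genes with a mean log2 CPM of at least 1 and an established symbol, the 8 largest rises were Ndufa4l2 (4.14 ± 0.56), the globins Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 (3.62 to 3.99), Vwf (3.91 ± 0.69), Lox (3.87 ± 0.57) and Eda2r (3.28 ± 0.34). The 8 largest falls were Wdr86 (-1.84 ± 0.46), Arl4d, Sik1, Nr4a1, Crabp2, Alox8, Insm1 and Epn3 (-1.32 ± 0.39). Slco1c1 also fell (-0.85 ± 0.23; -0.75 and not called without control normoxia replicate 1), and Wdr86 was not called without control normoxia replicate 4 (-1.61) nor Nr4a1 without control replicate 2 (-0.79) or knockout normoxia replicate 1 or 4 (-1.49 and -1.32). Sik1 and Epn3 lost their calls without most single libraries of these groups. In all, 2415 of 19854 genes were called, 1369 higher and 1046 lower, of which 691 and 87 changed at least 2-fold. Y-linked RNA was low in control normoxia replicates 3 and 4 and in no normoxic knockout. With it as a covariate, a fit chosen after seeing the data, fewer genes were called, as given below.

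Of 13 pan-reactive astrocyte genes, 11 rose and none fell (13 rose adjusted over the list alone). The list rose with adjusted p = 6.7e-17, and adjusted p = 0.151 with an estimated correlation. Of 12 genes of the neurotoxic reactive state, 4 rose (6 over the list alone), led by Ggta1 (1.13 ± 0.2) and Gbp2 (0.83 ± 0.2; 0.65 and not called without knockout normoxia replicate 3), with adjusted p = 0.00138, and adjusted p = 0.404 with an estimated correlation. Of 11 tested genes of the protective state, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with Cd109 at 1.9 ± 0.29 and Emp1 at 1.47 ± 0.29 (adjusted p = 0.00016; adjusted p = 0.329 with an estimated correlation). No gene of the 15 in the astrocyte homeostasis list passed, over all genes or adjusted over the list alone, and the list did not change (adjusted p = 0.891). Without knockout hypoxia libraries 1, 2 and 3, chosen after seeing the data, 2 of its genes were called. The mean log2 fold change was then 0.06 against 0.05.

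Of 15 antigen presentation genes 7 rose (9 adjusted over the list alone), among them H2-Aa (3.3 ± 0.45) and Cd74 (2.91 ± 0.38), the class II chain and its chaperone (adjusted p = 1.26e-08; adjusted p = 0.213 with an estimated correlation). Of 11 tested complement genes 9 rose (10 over the list alone), such as C3ar1 (2.19 ± 0.38) and C4b (1 ± 0.21), with adjusted p = 4.05e-09, and adjusted p = 0.213 with an estimated correlation. Cxcl10 (2.16 ± 0.3) and Cx3cl1 (1.53 ± 0.35), chemokines for T cells and microglia, were among 3 of 9 tested chemokine genes that rose (7 adjusted over the list alone; adjusted p = 9.86e-05; adjusted p = 0.161 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose by 1.66 ± 0.33, while Vegfa differed by 0.19 ± 0.31 and did not pass (adjusted p = 0.731). C3ar1 was low, at 1.13 to 2.81 CPM in the normoxic knockouts. Microglial markers also rose, as given below, and the cell types that the antigen presentation, complement and chemokine RNAs came from were not tested.

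Extracellular matrix genes rose in 8 of 16 cases (12 rose and 1 fell adjusted over the list alone), with Lox and the basement membrane collagen Col4a1 (1.86 ± 0.29) leading (adjusted p = 2.08e-08; adjusted p = 0.281 with an estimated correlation). Coagulation and fibrinolysis genes rose in 6 of 11 (7 over the list alone), including Anxa2 (1.26 ± 0.19) and Plau (1.48 ± 0.26), with adjusted p = 9.4e-05, and adjusted p = 0.213 with an estimated correlation. Of 11 iron and heme genes 5 rose and 1 fell (6 and 1 over the list alone). Among them were Hmox1, which breaks down heme (0.85 ± 0.15), and the iron exporter Slc40a1 (1.15 ± 0.24). The list had adjusted p = 0.00327, and adjusted p = 0.213 with an estimated correlation. Of 27 hypoxia-inducible factor targets 7 rose and 2 fell (10 and 3 over the list alone), with Pfkl at 0.46 ± 0.07 and Ddit4 at -0.96 ± 0.16 (adjusted p = 0.00362; adjusted p = 0.378 with an estimated correlation). Circadian clock genes fell in 3 of 12 (7 over the list alone), such as Tef (-0.38 ± 0.08) and Per1 (-0.8 ± 0.17), and cholesterol synthesis genes in 2 of 15 (3 over the list alone), Fdft1 (-0.45 ± 0.12) and Insig1 (-0.65 ± 0.2), neither of them called without knockout normoxia replicate 1 (-0.44 and -0.71) and several other single libraries. These lists had adjusted p = 0.000141 and 0.0111, and adjusted p = 0.213 and 0.627 with an estimated correlation.

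Mural (6 of 7 rose), microglial (6 of 9), endothelial (4 of 8 rose, 1 fell), erythroid (5 of 5), neuronal (2 of 9) and border macrophage markers (2 of 6) were higher as lists, with adjusted p = 5.27e-07, 1.22e-06, 0.00106, 5.18e-09, 0.000293 and 0.0199 in that order. Adjusted over the list alone, 6, 6, 5, 5, 7 and 2 rose and 1 endothelial gene, Slco1c1, fell. With an estimated correlation the adjusted p was 0.148, 0.213, 0.426, 0.213, 0.461 and 0.442. Rgs5, a pericyte gene, rose by 2.49 ± 0.32, Pecam1, an endothelial gene, by 2.31 ± 0.5, Trem2, a microglial gene, by 1.44 ± 0.25, and Slc17a7, a neuronal transporter, by 1.65 ± 0.35. The 13 mitochondrially encoded genes were higher as a list with no member passing (adjusted p = 0.00515), and choroid plexus and ribosomal protein genes lower with no member passing (adjusted p = 0.0122 and 0.0248; adjusted over the list alone 1 choroid plexus gene fell); with an estimated correlation the adjusted p was 0.686, 0.565 and 0.843. Without knockout hypoxia libraries 1, 2 and 3, chosen after seeing the data, 10 of 11 tested mitochondrially encoded genes were called, with a mean log2 fold change of 1.71 against 1.7, and so were 6 neuronal and 6 cholesterol genes. mt-Co1 (2.15 ± 0.72) was also called without any 1 of knockout hypoxia replicates 3 to 6 (2.15, 2.15, 2.17 and 2.15) or knockout normoxia replicate 2 (2.36). The interferon response (2 of 15 rose), NF-kB and adhesion (1 of 16 rose, 1 fell) and endothelial cavernoma response lists (2 of 13 rose) did not pass as lists (adjusted p = 0.574, 0.398 and 0.209), nor did they in hypoxia (adjusted p = 0.196, 0.385 and 0.98). In hypoxia the NF-kB and adhesion list was called higher without knockout hypoxia libraries 1, 2 and 3 (adjusted p = 0.0417), a choice made after seeing the data. Adjusted over the list alone 2, 3 and 5 rose and 0, 2 and 2 fell in normoxia. Of the 21 lists called, 0 were called with an estimated correlation, with 11 at an unadjusted p under 0.05, and 16 by fry. The gene count fell to 1122 without knockout normoxia replicate 3 to 1370 without knockout replicate 1, and to 1357, 1490, 1183 and 1552 without control normoxia replicates 1, 2, 3 and 4.

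**Figure D2:**
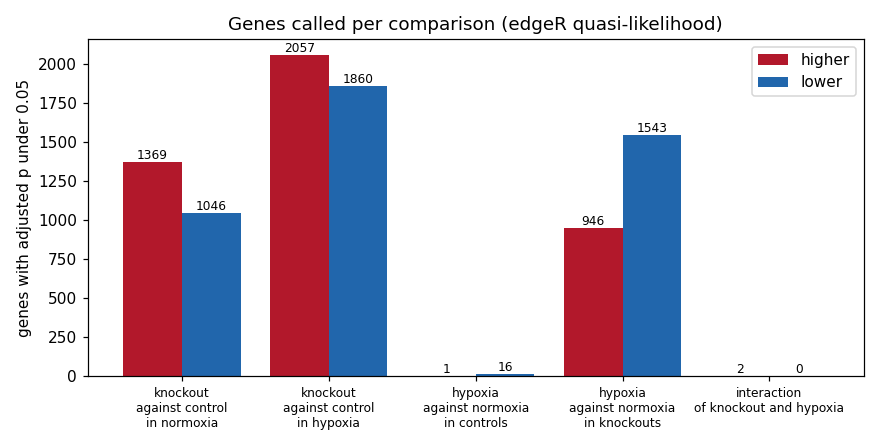
Bars show the number of genes with an adjusted p under 0.05 (edgeR), higher and lower, in each of the 5 comparisons. Hypoxia against normoxia gave 17 genes in controls and 2489 in knockouts, and the interaction gave 2.

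The second comparison asked the same in hypoxia. Gfap (1 ± 0.11) and Vim (1.36 ± 0.13) rose again. Under the same limits, the 8 largest rises were Ccl21a (6.77 ± 1.89), Ndufa4l2 (4.22 ± 0.53), the globins Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 (3.55 to 4.21), Pde3a (3.94 ± 0.41) and Eda2r (3.78 ± 0.33). The 8 largest falls were Dao (-2.46 ± 0.61), Rtp1, Fzd2 (-2.35 ± 0.24), Plin4, Tmem52, Myoc, Mfsd2a (-2.03 ± 0.21) and Pla2g3. Of 19854 genes 3917 were called, 2057 higher and 1860 lower. Ccl21a was at or under 0.0489 CPM in all control hypoxia libraries and in knockout libraries 4 to 7, and between 3.32 and 4.02 CPM in knockout libraries 1 to 3. Without those 3 it was not called (1.15), nor without control hypoxia replicate 4, 5 or 6 (6.42, 6.41 and 6.42). Dao was 19.7 CPM in control hypoxia replicate 3 and at most 2 CPM in the other controls, and without that library its log2 fold change was -0.34 and not called.

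Of 15 cholesterol synthesis genes 13 fell (15 adjusted over the list alone), Fdft1 by 1 ± 0.1 and Nsdhl by 0.71 ± 0.09 on the log2 scale (adjusted p = 6.7e-17; adjusted p = 0.198 with an estimated correlation). Of 15 astrocyte homeostasis genes 8 fell (12 over the list alone), such as the connexin Gjb6 (-1.17 ± 0.17) and glutamine synthetase, Glul (-0.63 ± 0.12), with adjusted p = 4.43e-08, and adjusted p = 0.426 with an estimated correlation. Pan-reactive genes rose in 6 of 13 (6 over the list alone), with adjusted p = 4.1e-07, and adjusted p = 0.258 with an estimated correlation. Protective state genes rose in 6 and fell in 1 of 11 (8 and 1 over the list alone), led by Ptgs2 (1.97 ± 0.31) and Cd109 (1.39 ± 0.27), with adjusted p = 0.0043, and adjusted p = 0.426 with an estimated correlation.

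Hypoxia-inducible factor targets rose in 13 and fell in 3 of 27 (14 and 4 adjusted over the list alone), with Pdk1 at 0.7 ± 0.07 and Pfkl at 0.47 ± 0.07 (adjusted p = 0.00168; adjusted p = 0.329 with an estimated correlation). Chemokines (Cxcl10 2.25 ± 0.28 and Cx3cl1 1.42 ± 0.32), complement (C3ar1 1.29 ± 0.34, not called without control hypoxia replicate 4 at 1.21, C1ra 1.23 ± 0.33) and antigen presentation genes (Ciita 1.82 ± 0.32, Cd74 1.6 ± 0.34) were higher as lists. They had 3 of 9, 5 of 11 and 7 of 15 members rising, 1 falling in the last, and 4, 9 and 7 adjusted over the list alone, with 2 falling in the last. Adjusted p was 0.0053, 0.00347 and 0.0364, and adjusted p was 0.213, 0.471 and 0.629 with an estimated correlation. Glucocorticoid response genes fell in 4 and rose in 1 of 9 (7 and 1 over the list alone), with Tsc22d3 at -1.7 ± 0.23 and Cdkn1a at 1.84 ± 0.39. Relative to all libraries, the list mean was -0.44 in control hypoxia replicate 6 and 0.24 to 0.59 in the other controls, 0.02 to 0.16 in knockouts 1 to 3 and -0.53 to -0.2 in knockouts 4 to 7. Without knockouts 1 to 3, chosen after seeing the data, its mean log2 fold change was -0.65 against -0.42. Circadian genes fell in 6 of 12 (6 over the list alone), with Npas2 at -0.72 ± 0.14 and Tef at -0.35 ± 0.07. For the glucocorticoid and circadian lists adjusted p was 0.011 and 0.000508, and adjusted p was 0.354 and 0.259 with an estimated correlation. The immediate early list was higher with 1 of 10 members passing, Egr1 (1.49 ± 0.34). The list had adjusted p = 0.0199, and adjusted p = 0.609 with an estimated correlation. Its mean relative to all libraries was 1.11 in control hypoxia replicate 6, above every hypoxic knockout (0.12 to 1.07). In the other controls it was -1.12 to -0.45, so the rise rests on those controls.

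Among markers of other cells, erythroid (5 of 5 rose), microglial (5 of 9), neuronal (6 of 9), mural (4 of 7), endothelial (2 of 8) and oligodendrocyte markers (2 of 7) were higher as lists and cerebellar genes lower (3 of 5 fell). Adjusted p was 1.06e-07, 0.000293, 0.000718, 0.00223, 0.0199, 0.033 and 0.00518 in that order. Adjusted over the list alone, 5, 5, 9, 6, 2 and 3 rose, with 1 mural gene falling, and 3 cerebellar genes fell. Slco1c1 (1.98 ± 0.22) was 1 of the 2 endothelial genes, and the other 7 markers had a mean of 0.52 (-0.17 to 1.12). The adjusted p was 0.213, 0.329, 0.486, 0.213, 0.562, 0.609 and 0.258 with an estimated correlation. Examples were Cx3cr1 (1.49 ± 0.22), Rgs5 (2.19 ± 0.3), Snap25 (1.49 ± 0.39) and Gdf10 (-1.82 ± 0.21). The cerebellar mean relative to all libraries was 1.26 in control hypoxia replicate 3 and 0.2 to 0.3 in the other hypoxic controls. In hypoxic knockouts it was -0.51 to 0.08, so the size of this fall depends in part on that control. Mitochondrially encoded genes rose in 10 of 13 (13 adjusted over the list alone; adjusted p = 0.00776; adjusted p = 0.699 with an estimated correlation). Knockout libraries 1, 2 and 3 stood apart in these RNAs. The mean of the mitochondrially encoded list was 2.89 to 3.59 log2 units above the mean of all libraries in those 3 and -1.17 to -0.65 in knockout libraries 4 to 7. Neuron markers were at 0.87 to 1.27 against -0.49 to 0.66. Without those 3 libraries, a choice made after seeing the data, 1696 genes were called (880 higher, 816 lower). The cholesterol, homeostasis and pan-reactive lists were called, with mean log2 fold changes of -0.52, -0.32 and 0.84 against -0.7, -0.62 and 0.88 with all libraries. The neuronal list had a mean of 0.44 against 1.02, with no member called. Members called fell from 4 to 1 in the mural, 5 to 3 in the microglial, 2 to 1 in the endothelial and 8 to 5 in the antigen presentation list, with means of 0.86, 0.67, 0.54 and 0.62 against 1.02, 0.74, 0.71 and 0.51. Fewer libraries may lower these counts. The mitochondrial and oligodendrocyte lists were not called (adjusted p = 0.357 and 0.517), with mt-Cytb at -0.22 and mt-Nd6 at -0.05 against 3.14 ± 0.97 and 2.86 ± 0.89 with all libraries. Both were also lost with the replicate number as a block (adjusted p = 0.117 and 0.0968), which added ependymal markers (adjusted p = 0.044) and lost the calls of Dao (-1.88), mt-Cytb (1.57) and mt-Nd6 (1.62). That block also joined normoxic libraries of the same number, and knockouts 1 and 2 had no hypoxic control of their number. It was therefore not a test of the 4 hypoxic pairs alone. The genes mt-Cytb and mt-Nd6 also lost their calls without any 1 control hypoxia library. Without the 3 libraries Egr1 (1.17), Snap25 (0.66), Esam (0.71) and Dao (-2.57) were not called and Vegfa was (0.65). Snap25 also lost its call without control hypoxia replicate 5 (1.36). Vegfa RNA was lower in knockouts 1 to 3 than in knockouts 4 to 7. It was higher in control hypoxia replicate 6 than in the other controls, so the Vegfa call depends on which libraries remain. Of the 19 lists called, 0 were called with an estimated correlation, with 7 at an unadjusted p under 0.05, and 13 by fry. The gene count was 2217 without control hypoxia replicate 4 and 2143 without replicate 5.

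**Figure D3:**
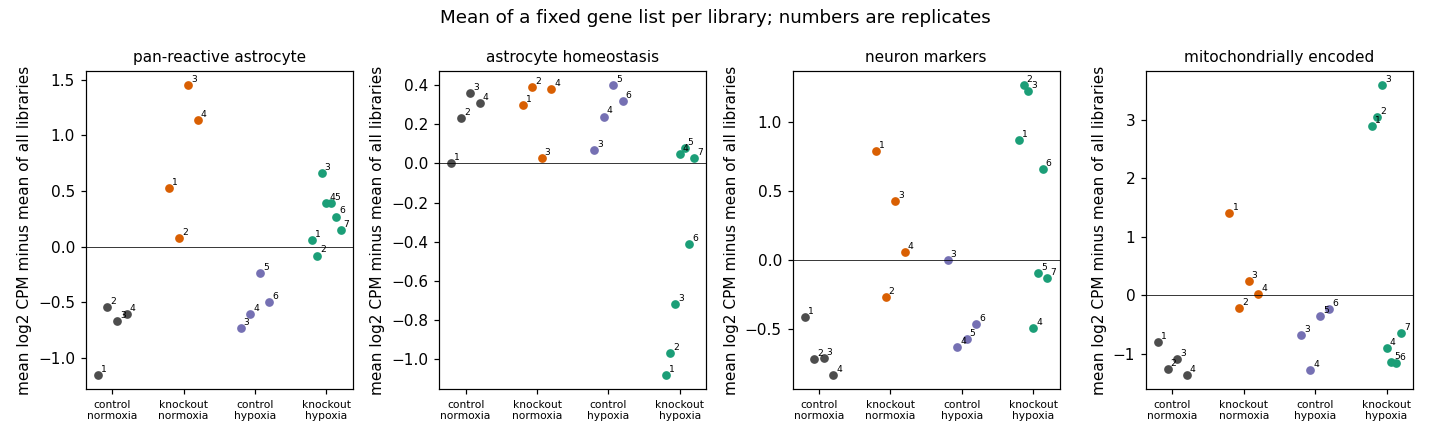
Mean log2 CPM of 4 gene lists in each library, relative to the mean of all 19 libraries, by group; small numbers are replicates. Knockout hypoxia replicates 1, 2 and 3 lie highest for mitochondrially encoded RNA (2.89 to 3.59) and lowest for astrocyte homeostasis (-1.08 to -0.72).

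The knockout effects at the 2 oxygen levels, which share no library, correlated across 19854 genes with Pearson r = 0.6 and Spearman rho = 0.539. Of the 2415 genes called in normoxia, 93.8% had the same sign in hypoxia. There were 777 genes higher in both, where independent lists would share 141.8, and 437 lower in both, where they would share 98. Only 5 were called in opposite directions. Eda2r, a death receptor of the tumour necrosis factor family, Ndufa4l2, Cxcl10, Gfap and Vim were among the genes higher in both.

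**Figure D4:**
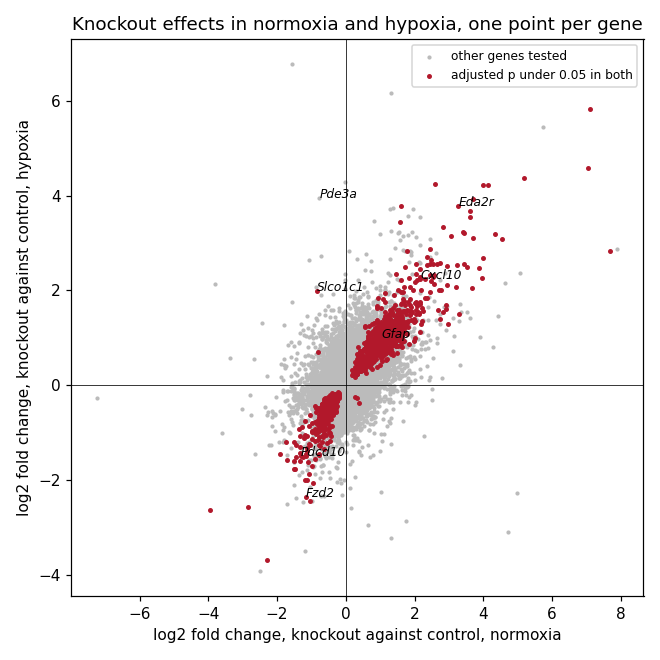
Each point is 1 of 19854 genes, placed by its log2 fold change between knockout and control in normoxia (x axis) and hypoxia (y axis); red genes have an adjusted p under 0.05 in both. Pearson r is 0.6, and Slco1c1 and Pde3a lie off the trend.

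The third comparison asked what hypoxia did in controls. Slco1c1, a thyroid hormone transporter whose promoter drives the recombinase, fell by 2.7 ± 0.24 on the log2 scale, from 697 ± 99.2 to 107 ± 13.9 CPM (n = 4 each), and Pde3a, a phosphodiesterase, from 36.1 ± 8.23 to 2.04 ± 0.515 CPM (log2 fold change -4.15 ± 0.43). Acacb (-1.05 ± 0.15), Trpm1 (-1.41 ± 0.21), Zfp970, Tmem82, Maml3 and Zik1 (-0.68 ± 0.12) also fell, and Ifit3b, an interferon-induced gene, rose by 0.72 ± 0.12. In all 17 genes were called, 1 higher and 16 lower, with 1788 at an unadjusted p under 0.05. Gfap (0.07 ± 0.12) and Vegfa (0.1 ± 0.31) did not pass. The count was 3, 4, 6 and 39 without control hypoxia replicates 3, 4, 5 and 6, 4 and 8 without control normoxia replicates 3 and 4, and 11 without knockout hypoxia replicate 5. Slco1c1, Pde3a and Acacb were called without any 1 library, while Trpm1 was not without control hypoxia replicate 3 or 4 (-1.39 and -1.31), and the other named genes each lost their call without at least 3 single libraries. DESeq2 called 140 genes and limma-voom 400; on simulated counts, for the knockout in normoxia, 16.5% of DESeq2 calls and 3.8% of limma-voom calls were false.

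As lists, ribosomal protein genes, erythroid genes and hypoxia-inducible factor targets were higher in hypoxic controls, and choroid plexus and endothelial markers lower. Adjusted p was 1.4e-10, 0.000698, 0.0159, 0.00327 and 0.0203. With an estimated correlation the adjusted p was 0.421, 0.378, 0.432, 0.483 and 0.564. None of their members was called except Slco1c1, which is in the endothelial list. The other 7 endothelial markers did not fall together: their log2 fold changes ranged from -0.48 to 0.51, with a mean of 0.08. The choroid plexus mean relative to all libraries was -2.64 in control hypoxia replicate 3 and -0.36 to 0.92 in the other hypoxic controls. In normoxic controls it was 0.02 to 1.83, so this fall depends largely on control hypoxia replicate 3. Adjusted over the list alone, 2 hypoxia-inducible factor targets rose, with the smallest p in Pfkl (0.31 ± 0.07) and Mxi1 (0.46 ± 0.11), and Slco1c1 fell. Of these 5 lists, 0 were called with an estimated correlation or by fry, and 0 had an unadjusted p under 0.05 with an estimated correlation. Without knockout hypoxia libraries 1, 2 and 3, chosen after seeing the data, the mitochondrially encoded and neuronal lists were also called higher (adjusted p = 0.000798 and 0.0343, against 0.113 and 0.102). With the replicate block the hypoxia-inducible factor list was not called (camera adjusted p = 0.677), while other lists were added, as counted below. The libraries of this comparison shared only a number.

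The fourth comparison asked what hypoxia did in knockouts. Vwf (-2.56 ± 0.53), Lox (-2.06 ± 0.43), Eps8l1, Stab2, Mfsd2a, a lipid transporter (-1.9 ± 0.21), Plin4, Fn1, fibronectin (-1.79 ± 0.35), and Cbr2 were the 8 largest falls under the same limits. Cbr2 was 29.1 CPM in knockout normoxia replicate 4 and not called without it (-0.4), and Eps8l1 was not called without knockout normoxia replicate 2 or 3 (-1.86 and -1.37). The 8 largest rises were the activity-induced Egr2 (2.3 ± 0.48), Nr4a1 (1.59 ± 0.37) and Egr1 (1.39 ± 0.34), with Kalrn, Miat, Lrguk, Neurod6 and Hpca. The immediate early mean relative to all libraries was -0.53 to 0.18 in normoxic knockouts. It was 0.12 to 0.51 in hypoxic knockouts 1 to 3 and 0.43 to 1.07 in 4 to 7. Hypoxic controls also varied, with 1.11 in replicate 6 and -1.12 to -0.45 in the others, so the size of this rise depends on the libraries. Miat, Neurod6 and Hpca, the second a neuronal transcription factor, each lost their call without several single libraries, among them knockout hypoxia replicate 2 (1.24, 1.11 and 1.02) and 3 (1.31, 1.08 and 1.02). Aldh1l1 fell (-0.55 ± 0.11). Of 19854 genes 2489 were called, 946 higher and 1543 lower. Slco1c1 (0.13 ± 0.2), Gfap (0.05 ± 0.11) and Vegfa (0.14 ± 0.28) did not pass.

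Extracellular matrix genes fell in 10 of 16 (13 adjusted over the list alone), Col4a1 by 1.58 ± 0.24 on the log2 scale, with adjusted p = 1.14e-10, and adjusted p = 0.213 with an estimated correlation. Astrocyte homeostasis genes fell in 6 of 15 (13 over the list alone), such as Gjb6 (-0.91 ± 0.17), and cholesterol synthesis genes in 9 of 15 (11 over the list alone). Adjusted p was 5.15e-10 and 8.99e-09, and adjusted p was 0.354 and 0.26 with an estimated correlation. Coagulation (5 of 11 fell), antigen presentation (5 of 15), complement (2 of 11), neurotoxic state (3 of 12), pan-reactive (4 of 13), iron and heme (3 of 11), astrocyte (3 of 9), endothelial (3 of 8), border macrophage (2 of 6) and fibroblast lists (3 of 6) were also lower. Over the list alone 6, 10, 6, 5, 7, 3, 3, 4, 3 and 3 fell. Adjusted p was 0.000508, 0.000508, 0.000698, 0.00281, 0.00876, 0.0167, 0.00345, 0.00327, 0.00365 and 0.000456, and with an estimated correlation the adjusted p was 0.258, 0.426, 0.426, 0.426, 0.553, 0.259, 0.483, 0.458, 0.359 and 0.329.

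Examples of these falls were H2-K1 (-0.69 ± 0.17; -0.55 and not called without knockout hypoxia libraries 1, 2 and 3), Steap4 (-2.15 ± 0.5), Cdh5 (-1.17 ± 0.22), Mrc1 (-0.99 ± 0.2) and Col1a1 (-1.2 ± 0.24). Higher were the ribosomal protein (10 of 36 rose), immediate early (3 of 10), cell cycle (2 of 10) and hypoxia-inducible factor lists (5 rose, 1 fell of 27), and erythroid and oligodendrocyte markers, with no member passing in the last pair. Over the list alone 16, 3, 4, 8, 0 and 3 rose, and 4 hypoxia-inducible factor targets fell. Both cell cycle members lost their calls without most single libraries, and without knockout hypoxia libraries 1, 2 and 3 (0.59 and 0.7). Adjusted p was 9.52e-09, 0.00142, 0.00911, 0.0364, 0.0315 and 0.0364, and with an estimated correlation the adjusted p was 0.442, 0.461, 0.488, 0.483, 0.565 and 0.609. Pdk1 rose by 0.35 ± 0.07 and Slc2a1, a glucose transporter, fell by 0.73 ± 0.14 on the log2 scale. With the replicate block the hypoxia-inducible factor list was not called (camera adjusted p = 0.426). The endothelial cavernoma response, mitochondrially encoded and neuronal lists then were (camera adjusted p = 0.0149, 0.0107 and 0.0383). The libraries of this comparison shared only a number. Without knockout hypoxia libraries 1, 2 and 3, chosen after seeing the data, 1394 genes were called, the astrocyte, oligodendrocyte and erythroid lists were not (adjusted p = 0.19, 0.786 and 0.357), and the mitochondrially encoded list, not called with all libraries (adjusted p = 0.169), was lower (adjusted p = 1.04e-09), as was the mural list (adjusted p = 0.0277, against 0.1). The mean log2 fold change of the homeostasis and cholesterol lists was then -0.35 and -0.28, against -0.64 and -0.45 with all libraries. Members called fell from 5 to 2 in coagulation, 5 to 0 in antigen presentation, 2 to 1 in complement, 3 to 1 in the neurotoxic state, 4 to 2 in the pan-reactive, 10 to 6 in the matrix, 9 to 5 in the cholesterol and 10 to 3 in the ribosomal protein list. Apart from cholesterol, the mean log2 fold changes of these lists moved little: -0.79, -0.38, -0.58, -0.51, -0.74, -0.91 and 0.23 in that order, against -0.7, -0.49, -0.61, -0.49, -0.69, -1 and 0.26. Those of the astrocyte, oligodendrocyte and erythroid lists went from -0.37, 0.51 and 1.11 to -0.14, 0.04 and 0.38. Fewer libraries may also lower the counts. Egr1 (1.06), Hpca (0.5), Neurod6 (0.59), Miat (0.18), Cbr2 (-1.7) and Eps8l1 (-2.21) lost their calls. The 19 lists gave 0 calls with an estimated correlation, with 4 at an unadjusted p under 0.05, and 11 by fry, and the gene count was 1480 without knockout normoxia replicate 1 and 1585 without replicate 2.

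The hypoxia effects in controls and knockouts, which share no library, correlated across genes with Pearson r = 0.263 and Spearman rho = 0.275. Of the 17 genes called in controls, 10 were lower in both, where independent lists would share 1.2. The test of the difference itself called 2 genes, Pde3a (interaction log2 4.71 ± 0.54) and Slco1c1 (2.83 ± 0.31), both with adjusted p = 0.000652, and 2292 genes had an unadjusted p under 0.05. The interaction gave 23 genes without control hypoxia replicate 6, and 108 by DESeq2, whose calls were 16.5% false on counts simulated for the knockout in normoxia. Among lists, 16 differed, 13 lower and 3 higher in hypoxic knockouts than both effects together would give. They were led by astrocyte homeostasis (median log2 -0.75; adjusted p = 9.92e-11; adjusted p = 0.329 with an estimated correlation), cholesterol synthesis (median -0.45; adjusted p = 1.4e-10; adjusted p = 0.213 with an estimated correlation) and extracellular matrix genes (median -0.87; adjusted p = 2.03e-08; adjusted p = 0.281 with an estimated correlation). None of their members was called over all genes, and 1, 8 and 7 were lower adjusted over the list alone. With the replicate block Msmo1, a cholesterol synthesis gene, was called (-1.04). The block also lost the cerebellar and oligodendrocyte lists (camera adjusted p = 0.102 and 0.126) and added the glucocorticoid list as lower (camera adjusted p = 0.026). In normoxia the replicate numbers were not taken as pairs. With an estimated correlation 0 lists were called and 4 had an unadjusted p under 0.05, and fry called 3. Without knockout hypoxia libraries 1, 2 and 3 the oligodendrocyte list and the astrocyte and cerebellar lists were not called (adjusted p = 0.32 and 0.0698 for the last pair). Their mean log2 values were 0.02, -0.12 and -0.81, against 0.48, -0.35 and -0.81 with all libraries, so only the cerebellar mean did not move. The mitochondrially encoded list was lower (adjusted p = 1.13e-17, against 0.662 with all libraries), as were the neuronal and mural lists (adjusted p = 0.00585 and 0.0292, against 0.94 and 0.0589). The mean log2 value of the homeostasis and cholesterol lists was then -0.37 and -0.31, against -0.67 and -0.48. That fit keeps control hypoxia replicate 3, where the cerebellar mean relative to all libraries was 1.26. In the other hypoxic controls it was 0.2 to 0.3, so the cerebellar value depends in part on that replicate.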

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

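The tests in this part were chosen after the results were seen, except the comparison of mitochondrially encoded with neuronal RNA in the other libraries and the counts over other splits of the samples; among these, the list count over splits that part the pairs was added after the results were seen.

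Slco1c1 and Pde3a were the only genes called as different between the 2 hypoxia effects, with interaction log2 values of 2.83 and 4.71, since both were low only in the control hypoxia libraries. A general effect of hypoxia is argued against: in knockouts the lower 95% bound of the log2 fold change with hypoxia was -0.29 for the lower of both genes, by edgeR. The pair lies close together, with 2 annotated genes between them, and of 9 tested neighbours 0 were called in the interaction by edgeR. A candidate explanation is a transgene spanning both genes, carried by the other 3 groups and not by these controls; another is a response to hypoxia that needs Pdcd10. They cannot be told apart, because the labels give no carriage per sample.

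Pdcd10 fell by 1.32 in normoxia and by 1.5 in hypoxia on the log2 scale in RNA dominated by astrocyte genes. Loss in contaminating endothelial RNA alone is argued against: in controls the median endothelial marker was at most 0.472% of the median astrocyte marker. Recombination in the astrocytes themselves stays open as a hypothesis, since the Slco1c1 gene measured at least 94.1 CPM in every library. The counts cover whole genes, so a loss of the deleted exons was not tested, and these cannot be told apart from lower expression.

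Knockout hypoxia libraries 1, 2 and 3 held more mitochondrially encoded and neuronal RNA than libraries 4 to 7. A smaller astrocyte share that raises every other cell type alike is argued against, as 5 of 13 other cell types had none of the 3 libraries above the highest of the other 4. Neuronal, oligodendrocyte and mural markers had all 3 above, and astrocyte markers were lower in these 3 (-0.7 to -0.49 against -0.16 to 0.17), so a lower astrocyte share beside a change in other cells stays open. Carry-over of RNA not bound to tagged ribosomes remains possible: in the 16 other libraries both means rose together around the group means with Pearson r = 0.44 (permutation p = 0.174, within groups, two-sided) and Spearman rho = 0.49 (permutation p = 0.102), and r was 0.17 without the 2 farthest libraries, so these values cannot be told apart from no relation. No biological explanation was tested, because the design gives no group within these knockouts.

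The interaction was also called for 16 lists at the preset correlation, and for none of them with an estimated correlation (adjusted p = 0.213 to 0.609), with mean log2 values of -0.91 for pan-reactive, -0.55 for neurotoxic state, -0.67 for astrocyte homeostasis, -0.58 for antigen presentation, -0.56 for complement, -0.87 for matrix, -0.78 for coagulation, -0.35 for iron and heme, and -0.48 for cholesterol genes. The means were -0.35 for astrocyte, -0.65 for border macrophage, -0.56 for fibroblast and -0.81 for cerebellar markers, and 0.67 for immediate early, 0.48 for oligodendrocyte and 1.02 for choroid plexus genes. Control hypoxia replicate 3 lay apart from the other hypoxic controls in cerebellar (1.26 against 0.2 to 0.3) and choroid plexus genes (-2.64 against -0.36 to 0.92). Both values depend in part on that library. The immediate early list varied within both hypoxic groups, as given above. The replicate block lost the cerebellar and oligodendrocyte calls (camera adjusted p = 0.102 and 0.126) and added the glucocorticoid list (camera adjusted p = 0.026).

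Single libraries stood apart from their group in 29 of 343 gene and group combinations (8.5%), where chance gives about 5%. In normoxic knockouts, replicate 3 was highest for Gfap (13600 CPM), Pdk1 (71.9), C3ar1 (2.81) and Emp1 (9.14), and replicate 1 was highest for Kalrn (328) and Cd163 (5.74) and lowest for H2-K1 (36.1) and Rpl11 (1.43). Replicate 2 was lowest for Plat (26) and Clic6 (23.1), and replicate 4 highest for Cbr2 (29.1). In normoxic controls, replicate 2 was highest for Nr4a1 (134), Per1 (377) and Emp1 (2.42), replicate 4 for Esam (0.686), and replicate 1 lowest for Cd109 (0.873). In hypoxic controls, replicate 6 was lowest for Plin4 (4.55) and Pde3a (1.27) and highest for Xist (0.492). Replicate 3 was highest for Dao (19.7, against at most 2 in the others) and Ccl21a (0.0489) and lowest for Acacb (5.81), and replicate 5 highest for C1ra (0.691). In hypoxic knockouts, replicate 3 was highest for Ndufa4l2 (44.8) and Vim (749) and lowest for Npas2 (27.5), replicate 6 was highest for Col4a2 (18) and lowest for Tsc22d3 (279), and replicate 5 highest for Mrc1 (6.28).

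Other splits of the same libraries tested chance. For knockout against control in normoxia (2415 genes, the highest other 2), only 1 of 35 splits, the real one, was as large. The same held for hypoxia in controls (17 genes, the highest other 0). This share lies under the limit of 0.05 set beforehand and argues against chance. It is also the smallest share that 35 splits can give, and the split tests were not corrected for their number. Chance is therefore not called excluded. For hypoxia in knockouts only 1 of 100 splits drawn, the real one, reached 2489 genes. Other splits drawn gave 2462, 2429 and 2250 genes, which points to a structure of these samples. That count is therefore not taken to argue against chance. For knockout against control in hypoxia, where the numbers were taken to pair libraries, the 16 splits that part the 4 pairs are too few for a share under 0.05. The real counts were 3917 genes and 19 lists, and the highest other was 0 genes and 19 lists. Splits that ignore the pairs reached 3917 genes in 2 of 100 cases and 19 lists in 4 of 100 (the highest other 22). The split that set knockouts 1, 2, 3 and 6 against the rest gave 6467 genes, which points to a structure of these samples. For the interaction count of 2, 3 of 100 regroupings were as large and the highest other was 2850, again a structure of the samples. For lists, chance is not excluded for knockout against control in normoxia (21; 4 of 35, 23), hypoxia in controls (5; 33 of 35, 17), hypoxia in knockouts (19; 9 of 100, 23) or the interaction (16; 23 of 100, 23). For the correlations of knockout and hypoxia effects 1 of 100 regroupings reached 0.6 (the highest other 0.587) and 1 of 100 reached 0.263 (the highest other 0.219). These regroupings, like those for the interaction, ignore the pairs in hypoxia, so they leave open what the pairs share.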

How the results depend on the processing

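The fits without knockout hypoxia libraries 1, 2 and 3, and those with a covariate, were chosen after seeing the data; all other alternatives were fixed before the data were examined. RLE scaling and both other filters on low counts moved no count by more than 1.5 times. DESeq2 called 140 genes for hypoxia in controls and 108 for the interaction, and limma-voom 400 for hypoxia in controls and 1197 in knockouts; fits of the 2 groups alone gave 35 and 981. With an absolute log2 fold change of at least 1 the counts were 778 and 879 for the knockout in normoxia and hypoxia and 11 and 247 for hypoxia in controls and knockouts. With an estimated correlation camera called 0 lists in each of the 5 comparisons, and fry 0, 11 and 3 for hypoxia in controls, in knockouts and the interaction. With the replicate block, 14 lists changed with hypoxia in controls, the interaction gave 9 genes and the correlation of hypoxia effects was 0.42. In the hypoxia comparisons, and for the knockout in normoxia, the libraries shared only a number, and not every library correlated best with its own number; the block moved no other count by more than 1.5 times. The correlation of knockout effects was 0.539 by Spearman, and over genes with a mean log2 CPM of at least 3 the correlations were 0.713 and 0.325. Without knockout hypoxia libraries 1, 2 and 3 the counts were 1696 for the knockout in hypoxia and 37 and 1394 for hypoxia in controls and knockouts, the correlation of knockout effects was 0.547, and mt-Cytb and mt-Nd6 turned to -0.22 and -0.05 for the knockout in hypoxia. With the neuron marker mean as a covariate these were -0.25 and -0.18, and the counts 1163 for the knockout in hypoxia, 67 and 3903 for hypoxia in controls and knockouts, and 528 for the interaction. With Y-linked RNA as a covariate the counts were 1422 for the knockout in normoxia and 11 for hypoxia in controls. Leaving out each library gave 1122 to 3149 and 2143 to 4744 genes for the knockout in normoxia and hypoxia, 3 to 39 and 1480 to 2715 for hypoxia in controls and knockouts, 2 to 23 for the interaction, and correlations of 0.531 to 0.617 and 0.194 to 0.327. Apart from fewer libraries where some were left out, the cause was not tested. Depth limits genes of few counts, and simulated changes of 1.5-fold were recovered in 49.3% of genes for the knockout in normoxia and 23.9% for the interaction.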

Other observations

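The tests of p53 targets were chosen after Cdkn1a, Eda2r, Pmaip1 and 5 other targets named here had been seen, and what they should show was written before the values of the 18 further targets were examined.

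Genes of the p53 response were among those higher in knockouts. Cdkn1a, a cell cycle inhibitor, rose by 2.31 ± 0.43 on the log2 scale in normoxia and 1.84 ± 0.39 in hypoxia, Eda2r by 3.28 ± 0.34 and 3.78 ± 0.33, and Pmaip1, a cell death gene, by 2.45 ± 0.34 and 2.88 ± 0.33. Phlda3 rose by 1.26 ± 0.21 and 1.5 ± 0.19 and Ccng1 by 0.49 ± 0.12 and 0.62 ± 0.11. Zmat3 and Trp53inp1, also p53 targets, passed in neither comparison, and Mdm2 passed in hypoxia (0.27 ± 0.07) and not in normoxia (-0.16 ± 0.07), while the difference between both did not pass (adjusted p = 0.2097; edgeR). The hypothesis that the response rises as a whole was tested on 18 other targets. In normoxia 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera p = 0.00965, p = 0.0575 with an estimated correlation), and in hypoxia 8 rose and 1 fell (9 and 2; camera p = 0.000141, p = 0.00822 with an estimated correlation). Bbc3 rose by 1.5 and 1.42, Tnfrsf10b by 1.37 and 1.26, and Psrc1 by 2.03 and 2.35, while Sesn1 fell by 0.76 and 0.67 on the log2 scale. A rise of p53 targets in knockouts may thus be a feature of these libraries, and the cell type it comes from was not tested.

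Control hypoxia replicate 6 differed from the other 3 control hypoxia libraries in several genes, and no group in the labels separates it from them. Fos, an immediate early gene, was 303.9 CPM there and 23.96 to 37.85 CPM in replicates 3 to 5, with 45.86 to 58.55 CPM in knockout hypoxia libraries 1 to 3 and 166.4 to 284.4 CPM in libraries 4 to 7. Fkbp5, induced by glucocorticoids, was 28.17 CPM there and 131.6 to 180.5 CPM in the other 3, with 82.94 to 100.5 CPM in knockouts 1 to 3 and 22.82 to 33.69 CPM in knockouts 4 to 7. Vegfa was 174 CPM there, 91.11 to 106.6 CPM in the other 3, 73.54 to 80.25 CPM in knockouts 1 to 3 and 179.9 to 187.2 CPM in knockouts 4 to 7, while Pdcd10 was 27.87 CPM there, in the range of the controls. Ddx3y was 0 CPM in that library.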
